A study of Macaca mulatta and Homo sapiens with 70 samples.

How the data were processed

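Sorted T cell subsets of rhesus macaques and humans were profiled by sequencing the 3′ ends of their messenger RNA. Per the labels' protocols, 2000 sorted cells per sample were flash frozen in lysis buffer, RNA was extracted with a column kit, and libraries were prepared with the QuantSeq 3′ mRNA-Seq forward kit, which reads 1 tag near the polyadenylated end of each transcript. The protocol also names 500 ng of total RNA as input, an amount given without a statement of how it relates to the sorted cells. The sources used here do not mention molecular identifiers. Each read of such a library stands for a transcript end, so gene length does not scale the counts.

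The values analysed are the whole read counts per gene that the authors deposited, 1 file per library, without normalization. Per the submitters' processing notes, STAR 2.7.3a, MultiQC, edgeR 3.30.3, limma 3.44.3 and R 4.0.1 were used, with the macaque build Mmul_10. The human build, both annotations, the read counter, its strand setting and its treatment of reads shared by near-identical genes are not given in the sources used here. Counts of paralogs, pseudogenes and overlapping genes are uncertain to that extent. The human files hold 58051 rows with 56305 distinct gene names, and the macaque files 18281 rows. The 1995 human rows whose name occurs more than once were left out of the gene lists, the named genes and the species comparison. In each file 4 rows name no gene (reads without a feature, ambiguous, multimapping or unmapped). They were kept out of library sizes and tests, and held 28.0% to 69.9% of reads in macaque libraries (median 32.8%) and 18.1% to 24.1% in human libraries (median 20.9%). Libraries had 8826 to 11630 genes detected in macaque and 15272 to 22902 in human. A pair of tables that repeat the counts for the whole series was not used, apart from the header of the macaque table.

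Groups were taken from the labels as species, tissue and sorted subset, with 4 libraries per group in macaque and 3 in human. The middle number of each title served as replicate number. The labels do not say what this number stands for. The libraries with serial numbers 10 and 20 both carry number 2 in macaque blood B7- CD8 cells, and the header of the macaque table gives number 1 to serial number 10. Within each group, chi-square statistics of the counts of each pair of libraries were at least 25.9 times their degrees of freedom, so no pair looked like a repeated deposit of 1 library. This covers counting error only and does not show that libraries came from separate samples. Every library was counted as a replicate, as the labels list them.

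Each species was fitted separately with edgeR 4.0.16 in R 4.3.3, all 10 groups in a single quasi-likelihood fit with 1 mean per group and TMM scaling factors. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 12647 macaque and 17984 human genes. The 24 contrasts were gut against blood within each sort, B7+ against B7- within each tissue and lineage, the mean of blood B7+ and B7- against naive cells, and the tissue by B7 interaction. A gene was called risen or fallen at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene comes from this test unless another tool is named. The error beside a log2 fold change is its size divided by the square root of the F statistic. Expression levels are TMM-scaled CPM, counts per fixed number of reads assigned to genes, over all genes, as mean ± SD over the libraries of a group. Genes were compared between species by symbol, among 11624 tested in both.

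The 28 gene lists were written from general knowledge of T cells before the data were examined, and none was chosen on these samples. They cover the CD4 and CD8 lineages, genes that a B7 label could name (ITGB7, CD80 and CD86), tissue residency, recirculation and egress, naive cells, homing receptors and integrins, type 17, type 1, type 2, follicular helper and regulatory T cells, cytotoxicity, inhibitory receptors, immediate early genes, heat shock, interferon response, virus restriction, TGF-beta response, proliferation and glycolysis. The others are markers of cells outside the sort: epithelium, B and plasma cells, myeloid cells, stroma and endothelium, mast cells, NK and gamma-delta T cells, red cells and platelets. Macaque genes missing under a list's symbol were looked up among the synonyms of the macaque gene table. RIPOR2 was not matched, and its former symbol FAM65B stands in the files. Each list with at least 3 tested members was tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01, on log2 CPM with a prior count of 2), adjusted over the lists of a contrast. Of 660 such tests 251 passed, and 97 of these also passed with a correlation estimated from the data. Where a list is said to pass and only the first p is given, it passed with the estimated correlation too. Camera compares a list with the other genes, so a list can pass with few of its members called.

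The design, the tests, the lists, the rule for naming genes and all alternatives except the last 2 below were chosen before the data were examined. The rule named CD4, CD8A, CD8B, ITGB7, CD80 and CD86 as label checks, the 4 tested members of each list with the smallest p, and the 8 risen and 8 fallen genes with the smallest p among those called with a log2 fold change of at least 1 in size. For the species comparison it named the 8 risen and 8 fallen shared genes with the smallest larger p. The alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE scaling factors, no low-count filter, the replicate number as a block, the block with serial number 10 as number 1, leaving out each library in turn, leaving out libraries under 25% of the species' median depth, an adjusted p under 0.01 in both species, and list tests with an estimated correlation or with the block. After the data were seen, fits without the foreign-marker libraries and without the low-complexity libraries were added.

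Whether replicate numbers pair libraries was checked by correlating deviations from the group means, for comparisons of 2 groups before the calls of the blocked fits were compared and for the others afterwards. Every pair was correlated above 0.1 in 3 comparisons, B7+ against B7- in human blood CD4 cells (0.14 to 0.18) and in human gut CD8 cells (0.27 to 0.52), where the blocked count is given, and human CD4 cells against naive cells (0.12 to 0.18), whose count moved by less than 1.5 times with the block. The pairing there comes from the data, not the labels. In the others at least 1 pair lay at or under 0.1 (human gut CD4 -0.067 to 0.60), and libraries were treated as unpaired. A pairing is not excluded, as most libraries deviated most like their own number.

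The fit was tested on counts simulated from the real means and library sizes, with 200 genes changed 2-fold, 4-fold or 8-fold. For gut against blood in macaque B7- CD4 cells (12647 genes), edgeR recovered 1.47% of the genes changed 2-fold, 24.2% of those changed 4-fold and 45.7% of those changed 8-fold, with 4.0% of its calls false. For B7+ against B7- in macaque gut CD4 cells it recovered 4.23%, 35.9% and 50.8%, with 3.28% false. For B7+ against B7- in human gut CD4 cells (17984 genes) it recovered 20.9%, 50.0% and 60.3%, with 1.12% false, and for the macaque CD4 interaction 1.54%, 20.3% and 32.4%, with 9.76% false. On the same simulated counts 54.9%, 54.6%, 35.0% and 64.5% of the calls of DESeq2 were false in these 4 comparisons, and 30.4%, 33.3%, 33.6% and 11.1% of those of limma voom with quality weights. XIST and Y-linked genes were left out of the named genes and lists, and the values of 1 further gene are not reported here.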

Results

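Messenger RNA was sequenced from its 3′ end in 70 libraries, each made from 2000 T cells sorted from blood or from rectal biopsies (gut) of rhesus macaques and humans. In each species 10 sorted subsets were sampled. These were naive CD4 and naive CD8 cells of blood, and CD4 and CD8 cells of blood and gut sorted as B7+ or B7-. The labels do not spell out what B7 stands for. There were 4 libraries per subset in macaque and 3 in human. Nothing in the labels says that the libraries of a subset came from separate animals or donors, so every p-value measures the spread between these samples, which may be technical. Macaque libraries held 4556031 to 13578912 reads assigned to genes (median 11732000) and human libraries 10519819 to 16002313 (median 13107990). A count of 3 reads corresponded to 0.221 to 0.658 CPM in macaque and to 0.187 to 0.285 CPM in human. Reads amplified by PCR without molecular identifiers are not independent molecules, so these floors cover counting error only. Libraries are named by their group and replicate number, except that 2 libraries of macaque blood B7- CD8 cells carry number 2 and are named by their serial numbers, 10 and 20. The stated aim was to compare expression profiles between the blood and gut compartments.

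CD4 and CD8B separated the CD4 from the CD8 sorts. CD4, the co-receptor of helper T cells, was at 675 ± 58.5 CPM (mean ± SD, n = 4) in macaque blood B7+ CD4 cells and at 4.33 ± 6.97 CPM in blood B7+ CD8 cells. CD8B, a chain of the cytotoxic T cell co-receptor, was at 5.07 ± 7.38 and 1121 ± 238 CPM in the same 2 subsets. In human blood B7+ cells, CD4 was at 698 ± 114 CPM in CD4 cells and 6.57 ± 4.11 CPM in CD8 cells (n = 3), and CD8B at 5.96 ± 7.37 and 457 ± 151 CPM. Gut subsets carried the same contrast, with CD4 at 699 ± 169 CPM in macaque gut B7+ CD4 cells against 3.79 ± 5.07 CPM in gut B7+ CD8 cells. CCR7, a lymph node homing receptor of naive cells, was at 1645 ± 535 CPM in macaque naive CD8 cells and 770.2 ± 363 CPM in blood B7+ CD8 cells, and the difference of both blood CD8 sorts from naive cells did not pass the test there (adjusted p = 0.14, edgeR), though it did with voom and without the low-complexity gut libraries of the next paragraph.

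Markers of cells outside the sort were present in gut libraries. The 23 epithelial markers summed to 8628 ± 16808 CPM in macaque gut B7- CD4 cells, where 1 library held 33839 CPM, and to 11265 ± 15559 CPM in human gut B7- CD4 cells. No blood library exceeded 37.3 CPM in macaque or 64.5 CPM in human. The B cell and plasma cell markers summed to 6329.6 ± 6968 CPM in macaque gut B7+ CD4 cells and to 2331 ± 3543 CPM in human gut B7+ CD4 cells. The 7 libraries in which either sum exceeded 2000 CPM (4 macaque and 3 human, all from gut) are called the foreign-marker libraries below, and the 3 macaque gut libraries with fewer than 10000 genes detected the low-complexity libraries. Both limits were set after the data were seen. Markers of stroma and endothelium reached 1535 ± 1355 CPM in macaque gut B7- CD8 cells. Within sorts, lineage genes of the other lineage differed between tissues. CD8A was higher in gut than in blood CD4 cells of macaque B7+ (log2 difference ± SE 3.14 ± 0.73), human B7+ (2.91 ± 0.82) and human B7- sorts (3.38 ± 0.87), at 46.9 ± 44.9 CPM in macaque gut B7+ CD4 cells against 1302 ± 258 CPM in gut B7+ CD8 cells. CD8B was higher in gut B7- CD4 cells of macaque (4.16 ± 0.97), and CD4 lower in gut B7- CD8 cells of macaque (-3.40 ± 0.98). The largest adjusted p of these 5 differences was 0.033 (edgeR). The CD8A calls were lost without the foreign-marker libraries (2.15, 0.49 and 1.76). The human ones were each lost without gut replicate 7 (0.46 in B7+ and 2.33 in B7-), blood replicate 5 (2.73 and 3.03) or blood replicate 7 (2.55 and 3.25). The macaque CD8A call was lost without gut replicate 3 (2.23), that of CD8B without gut replicate 4 (1.07), and that of CD4 without any 1 of 7 of the 8 libraries, all but blood replicate 3 (-3.47 to -3.04). With voom all of these but CD8A in human B7- cells were lost.

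To compare the compartments, gut was set against blood within each sort. In macaque B7+ CD4 cells, several immediate early genes were among the genes with the smallest p. NR4A2, an orphan nuclear receptor induced by T cell receptor signalling, had a log2 fold change of 5.49 ± 0.53 (SE, n = 4 per group), and ZFP36, which promotes decay of cytokine transcripts, one of 2.95 ± 0.30. TNFAIP3, an inhibitor of NF-kappa-B signalling, rose by 3.83 ± 0.41, PER1, a circadian repressor, by 3.78 ± 0.37, and SRGN, the proteoglycan core protein serglycin of secretory granules, by 2.92 ± 0.23. The zinc finger gene ZNF331 rose by 4.60 ± 0.41 and RGS1, which dampens chemokine receptor signalling, by 5.17 ± 0.69. TXNIP, an inhibitor of glucose uptake, fell with a log2 fold change of -2.35 ± 0.33, as did TBC1D10C (-2.03 ± 0.22), PDLIM2 (-1.43 ± 0.16) and BIN2 (-2.21 ± 0.26). The largest adjusted p among these 11 genes was 5.1e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 505 of 12647 genes rose and 279 fell. Among the lists, immediate early genes rose (13 risen of 22, 18 adjusted over the list alone, camera adjusted p = 4.3e-29). Tissue residency genes rose too (9 risen of 22, 12 adjusted over the list alone, camera adjusted p = 3.8e-12), and 4 members of that list (CD69, NR4A1, NR4A2 and TNFAIP3) are also immediate early genes. Genes of recirculation and egress fell (7 fallen of 17, 11 adjusted over the list alone, camera adjusted p = 9.4e-07). Type 17 genes rose (6 risen of 16, 12 adjusted over the list alone, camera adjusted p = 3.8e-11), as did TGF-beta response genes (5 risen of 11, 5 adjusted over the list alone, camera adjusted p = 1.3e-07). B and plasma cell markers stood at 6329.6 ± 6968 CPM in gut against 115 ± 52.1 CPM in blood (2 risen of 15, 2 adjusted over the list alone, camera adjusted p = 0.0027 but adjusted p = 0.17 with an estimated correlation). The total of 784 called genes was 490 without blood replicate 3, and 1378 without the low-complexity libraries.

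In macaque B7- CD4 cells, ZNF331 (5.01 ± 0.42), NR4A2 (5.55 ± 0.53) and SRGN (2.66 ± 0.22) again rose, as did the splicing factor gene SRSF7 (1.82 ± 0.20) and the splicing kinase gene CLK1 (3.08 ± 0.34). TXNIP (-3.17 ± 0.34), TRAF3IP3 (-2.12 ± 0.21), TBC1D10C (-1.96 ± 0.22) and CHMP7 (-2.97 ± 0.36) fell. ITGB1, the integrin beta 1 chain, fell by 2.35 ± 0.36 on the log2 scale. The adjusted p values were at most 2.5e-05 (edgeR), and 783 genes rose and 702 fell. Immediate early genes rose (17 risen of 22, 20 adjusted over the list alone, camera adjusted p = 5.6e-22), residency genes rose (7 risen and 1 fallen of 22, 7 risen and 1 fallen adjusted over the list alone, camera adjusted p = 2.8e-06) and egress genes fell (7 fallen of 17, 9 adjusted over the list alone, camera adjusted p = 6.9e-04 but adjusted p = 0.068 with an estimated correlation). Type 17 genes (5 risen of 16, 7 adjusted over the list alone, camera adjusted p = 3.5e-04) and TGF-beta response genes (5 risen of 11, 5 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.0030) were higher in gut. Interferon response genes went down on balance (2 risen and 6 fallen of 25, 2 risen and 10 fallen adjusted over the list alone, camera adjusted p = 5.7e-05 but adjusted p = 0.11 with an estimated correlation). Epithelial markers moved with this comparison (20 risen of 23, 22 adjusted over the list alone, camera adjusted p = 3.7e-09 but adjusted p = 0.12 with an estimated correlation), at 8628 ± 16808 CPM in gut and 10.6 ± 3.90 CPM in blood. The total of 1485 was 976 without blood replicate 3.

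In macaque B7+ CD8 cells, ITGAE, the alpha E integrin chain that binds E-cadherin on epithelium, had a log2 fold change of 4.65 ± 0.51, and LDLRAD4, a TGF-beta feedback inhibitor, one of 4.11 ± 0.39. NFKB2 (4.82 ± 0.46), BTG2 (3.16 ± 0.30), NR4A2 (5.22 ± 0.52) and ZNF331 (4.85 ± 0.42) rose as well. KLF2, the transcription factor that drives S1PR1, fell by 4.10 ± 0.43 on the log2 scale, beside RASGRP2, an activator of the small GTPase RAP1 (-4.53 ± 0.57), PDLIM2 (-2.07 ± 0.17) and TBC1D10C (-2.44 ± 0.23). The adjusted p of these 10 genes was at most 1.2e-06 (edgeR). In total 439 genes rose and 208 fell in B7+ CD8 cells. Immediate early (14 risen of 22, 18 adjusted over the list alone, camera adjusted p = 1.5e-29) and residency genes (5 risen of 22, 9 adjusted over the list alone, camera adjusted p = 1.3e-10) rose, and egress genes fell (8 fallen of 17, 9 adjusted over the list alone, camera adjusted p = 1.1e-11). Type 17 genes rose (6 risen of 16, 10 adjusted over the list alone, camera adjusted p = 1.1e-06), as did TGF-beta response genes (5 risen of 11, 6 adjusted over the list alone, camera adjusted p = 5.3e-08). Epithelial markers stood at 919 ± 1301 CPM in these gut libraries (12 risen of 23, 18 adjusted over the list alone, camera adjusted p = 3.9e-10 but adjusted p = 0.17 with an estimated correlation). The total of 647 was 429, 423 and 425 without blood replicates 2, 3 and 4.

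RBM38, an RNA-binding protein gene, rose in gut B7- CD8 cells of macaque by 3.66 ± 0.31, VIM, which encodes vimentin, by 2.16 ± 0.22, SQSTM1, an autophagy receptor gene, by 2.47 ± 0.26, and NR4A2 by 6.15 ± 0.55. TXNIP (-3.63 ± 0.35), TRAF3IP3 (-1.98 ± 0.21), CAPG, an actin-capping protein gene (-3.17 ± 0.47), and ITGB1 (-1.68 ± 0.35) fell, with an adjusted p of at most 0.0021 over these 8 genes (edgeR). In all 412 genes rose and 174 fell. Immediate early genes rose (16 risen of 22, 18 adjusted over the list alone, camera adjusted p = 5.8e-36). Residency genes rose (7 risen of 22, 10 risen and 1 fallen adjusted over the list alone, camera adjusted p = 2.4e-08) and egress genes fell (6 fallen of 17, 9 adjusted over the list alone, camera adjusted p = 6.4e-06). Type 17 genes gave 1 risen of 16, 1 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.64. TGF-beta response genes rose (6 risen of 11, 6 adjusted over the list alone, camera adjusted p = 4.2e-08), and so did heat shock genes (4 risen of 11, 6 adjusted over the list alone, camera adjusted p = 6.5e-07). Stroma and endothelium markers stood at 1535 ± 1355 CPM in gut and 72.1 ± 64.2 CPM in blood (6 risen of 11, 8 adjusted over the list alone, camera adjusted p = 3.3e-11). The total of 586 was 382, 372 and 382 without the blood library of serial number 10, replicate 3 and replicate 4, and 989 without the low-complexity libraries.

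In human B7+ CD4 cells, CREM, a cAMP-responsive transcription factor, had a log2 fold change of 6.04 ± 0.41 (n = 3 per group), ZNF331 one of 3.57 ± 0.22 and NAMPT, an enzyme of NAD synthesis, one of 4.21 ± 0.33. SLC2A3, a glucose transporter gene, rose by 3.29 ± 0.22, BCL3, a regulator of NF-kappa-B, by 3.41 ± 0.24, NFE2L2, a regulator of the oxidative stress response, by 2.08 ± 0.15, and EZR, which encodes ezrin, by 1.96 ± 0.15. TXNIP fell by 3.00 ± 0.31 on the log2 scale, together with TRAF3IP3 (-1.98 ± 0.16), NOSIP (-2.12 ± 0.19), RCSD1 (-1.58 ± 0.15) and STMN3 (-2.29 ± 0.24). The largest adjusted p among these 12 genes was 6.4e-07 (edgeR). Over all 17984 genes tested, 1188 rose and 753 fell. Immediate early genes rose (19 risen of 22, 20 adjusted over the list alone, camera adjusted p = 1.0e-23), and residency genes rose (12 risen of 22, 17 adjusted over the list alone, camera adjusted p = 4.4e-12). Heat shock genes were higher (11 risen of 13, 12 adjusted over the list alone, camera adjusted p = 3.4e-09 but adjusted p = 0.13 with an estimated correlation), and TGF-beta response genes rose (8 risen of 11, 9 adjusted over the list alone, camera adjusted p = 3.6e-08). Egress genes were lower (1 risen and 6 fallen of 19, 1 risen and 7 fallen adjusted over the list alone, camera adjusted p = 6.4e-05 but adjusted p = 0.10 with an estimated correlation), and type 17 genes higher (4 risen of 16, 7 adjusted over the list alone, camera adjusted p = 8.3e-05 but adjusted p = 0.14 with an estimated correlation). Epithelial markers stood at 3225 ± 4421 CPM in gut (18 risen of 23, 21 adjusted over the list alone, camera adjusted p = 1.3e-09 but adjusted p = 0.21 with an estimated correlation). The total of 1941 was 1252, 1151 and 1127 without blood replicates 5, 6 and 7.

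Human B7- CD4 cells of gut were higher than those of blood in CREM (5.98 ± 0.41), ZNF331 (3.44 ± 0.22), YPEL5 (3.22 ± 0.25), GLA, the lysosomal alpha-galactosidase gene (3.25 ± 0.23), and SLC2A3 (2.99 ± 0.22). TXNIP (-3.74 ± 0.32), ARHGAP30 (-1.31 ± 0.11), RCSD1 (-1.72 ± 0.15), STMN3 (-2.32 ± 0.24) and ITGB1 (-2.14 ± 0.40) fell, with adjusted p at most 7.8e-04 over the 10 genes (edgeR). Over all tested genes 1171 rose and 718 fell. Immediate early genes rose (20 risen of 22, 20 adjusted over the list alone, camera adjusted p = 1.1e-22), as did residency genes (13 risen of 22, 16 adjusted over the list alone, camera adjusted p = 3.4e-10). Egress genes fell (11 fallen of 19, 1 risen and 13 fallen adjusted over the list alone, camera adjusted p = 6.5e-10) and TGF-beta response genes rose (5 risen of 11, 5 adjusted over the list alone, camera adjusted p = 3.3e-04). Heat shock genes were higher (10 risen of 13, 13 adjusted over the list alone, camera adjusted p = 4.2e-10 but adjusted p = 0.087 with an estimated correlation), and type 17 genes gave 2 risen of 16, 4 adjusted over the list alone, camera adjusted p = 0.0020 but adjusted p = 0.22 with an estimated correlation. Epithelial markers were at 11265 ± 15559 CPM in gut (18 risen of 23, 21 adjusted over the list alone, camera adjusted p = 3.2e-09 but adjusted p = 0.22 with an estimated correlation). The total of 1889 was 1113 without gut replicate 6, 1062, 1121 and 1170 without blood replicates 5, 6 and 7, and 658 without the libraries rich in foreign markers, which left 1 library in the gut group, assumed to vary like the others.

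In human B7+ CD8 cells, CREM (6.20 ± 0.41), YPEL5 (3.90 ± 0.26), ZNF331 (3.82 ± 0.22), BCL3 (3.43 ± 0.24) and LDLRAD4 (5.61 ± 0.63) rose. S1PR1, the receptor for the egress signal sphingosine-1-phosphate, fell by 1.81 ± 0.23 on the log2 scale, beside RASGRP2 (-2.02 ± 0.25), CCND3, which encodes cyclin D3 (-1.63 ± 0.18), and TXNIP (-3.27 ± 0.32). Over these 9 genes the adjusted p was at most 6.4e-06 (edgeR), with 951 genes risen and 595 fallen in all. Immediate early genes rose (16 risen of 22, 18 adjusted over the list alone, camera adjusted p = 3.4e-21), residency genes rose (10 risen of 22, 17 adjusted over the list alone, camera adjusted p = 3.7e-14) and egress genes fell (1 risen and 6 fallen of 19, 2 risen and 13 fallen adjusted over the list alone, camera adjusted p = 4.2e-09). The TGF-beta response list rose on balance (6 risen and 2 fallen of 11, 7 risen and 2 fallen adjusted over the list alone, camera adjusted p = 1.6e-05). Heat shock genes gave 11 risen of 13, 13 adjusted over the list alone, camera adjusted p = 4.9e-11 but adjusted p = 0.068 with an estimated correlation, and type 17 genes 3 risen of 16, 4 adjusted over the list alone, camera adjusted p = 0.061. Epithelial markers were at 307 ± 365 CPM (0 called of 23, 13 risen adjusted over the list alone, camera adjusted p = 0.0061 but adjusted p = 0.68 with an estimated correlation). Without blood replicates 5 and 7 the total of 1546 was 1003 and 1021, and without gut replicate 6 it was 993.

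IFNG, the gene of interferon gamma, rose in gut B7- CD8 cells of humans by 4.72 ± 0.66, PDCD1, the inhibitory receptor PD-1, by 2.79 ± 0.64, and CTLA4, another inhibitory receptor, by 2.81 ± 0.53. Among the genes with the smallest p, ZNF331 (3.96 ± 0.22), RBM38 (1.91 ± 0.14) and EZR (2.15 ± 0.15) rose. SAMHD1, a dNTP hydrolase that restricts lentiviruses, fell by 1.62 ± 0.18 on the log2 scale, beside RCSD1 (-1.66 ± 0.15), TXNIP (-3.15 ± 0.31) and ITGB1 (-2.42 ± 0.40). The largest adjusted p of these 10 genes was 0.0058 (edgeR), among 970 genes risen and 648 fallen. Immediate early (19 risen of 22, 21 adjusted over the list alone, camera adjusted p = 4.9e-26), heat shock (12 risen of 13, 13 adjusted over the list alone, camera adjusted p = 5.8e-15) and residency genes rose (11 risen of 22, 16 risen and 1 fallen adjusted over the list alone, camera adjusted p = 5.3e-13). Inhibitory receptors rose (5 risen of 11, 7 adjusted over the list alone, camera adjusted p = 0.0011), and TGF-beta response genes rose (6 risen of 11, 9 adjusted over the list alone, camera adjusted p = 2.0e-07). Egress genes were lower (2 risen and 7 fallen of 19, 2 risen and 8 fallen adjusted over the list alone, camera adjusted p = 1.3e-05 but adjusted p = 0.065 with an estimated correlation), and type 17 genes gave 2 risen of 16, 2 adjusted over the list alone, camera adjusted p = 0.42. Epithelial markers were at 522 ± 742 CPM (8 risen of 23, 15 adjusted over the list alone, camera adjusted p = 4.7e-04 but adjusted p = 0.61 with an estimated correlation). The total of 1618 was 1074 without blood replicate 6.

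The species were then compared over the 11624 genes tested in both under the same symbol. In B7+ CD4 cells, 353 genes were called in the same direction in macaque and human, 261 risen and 92 fallen, where independent lists of these sizes would share 42.4 and 14.3. The genes called in opposite directions were THYN1, HIP1R, CD27 and IL10RA. The shared genes were 526 in B7- CD4 cells (369 risen and 157 fallen, against 66.4 and 34.1 for independent lists), 297 in B7+ CD8 cells (239 and 58, against 31.4 and 8.90) and 289 in B7- CD8 cells (245 and 44, against 29.6 and 7.63). Opposite calls were made for SMPD2, STIP1, PSIP1, TRAPPC1 and ZMYND12 in B7- CD4 cells, THYN1, LGMN and XBP1 in B7+ CD8 cells and RNF125 in B7- CD8 cells. These 12 genes were named after their values were seen. The macaque and human log2 fold changes correlated across genes with Pearson's r of 0.39, 0.45, 0.36 and 0.42 and Spearman's rho of 0.37, 0.39, 0.34 and 0.38, in the order B7+ CD4, B7- CD4, B7+ CD8 and B7- CD8, and genes are not independent replicates. ZNF331 had log2 fold changes of 4.60 ± 0.41 in macaque and 3.57 ± 0.22 in human B7+ CD4 cells, TNFAIP3 of 3.83 ± 0.41 and 4.33 ± 0.40, and PER1 of 3.78 ± 0.37 and 4.32 ± 0.35. NFKB2, a subunit of the alternative NF-kappa-B pathway, rose by 4.82 ± 0.46 and 2.81 ± 0.24 in B7+ CD8 cells. TXNIP fell in both species in B7- CD4 cells (-3.17 ± 0.34 in macaque and -3.74 ± 0.32 in human), and so did FAM65B, an inhibitor of the GTPase RhoA (-2.22 ± 0.29 and -2.36 ± 0.29). CD27, a co-stimulatory receptor, had log2 fold changes of 2.55 ± 0.28 in macaque and -1.10 ± 0.32 in human B7+ CD4 cells. The human call was lost without any 1 of 5 of the 6 libraries (all but blood replicate 6) and without the foreign-marker libraries. At an adjusted p under 0.01 in both species the shared counts were 176, 206, 146 and 151. Without the foreign-marker libraries the count in B7- CD4 cells was 257.

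Across both species and all 4 sorts, 121 genes were risen in gut in each of the 8 tissue comparisons and 15 were fallen in each. The 121 held 10 of the 22 immediate early genes, where 0.229 would be expected from the list's share of genes tested in both species. They held 4 of 22 residency genes, but NR4A1, NR4A2 and TNFAIP3 are in both lists. They held 3 of 11 TGF-beta response genes (LDLRAD4, PMEPA1 and SKIL) and 3 of 15 glycolysis genes (SLC2A3, PFKFB3 and LDHA). CXCR4, a chemokine receptor, and RGS1 belonged to them, and so did 2 stroma markers, the collagen genes COL1A1 and COL3A1. The 15 fallen genes included TXNIP, RASGRP2, CCND3 and LEF1, a transcription factor of naive T cells. These genes were singled out after their values were seen.

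**Figure D1:**
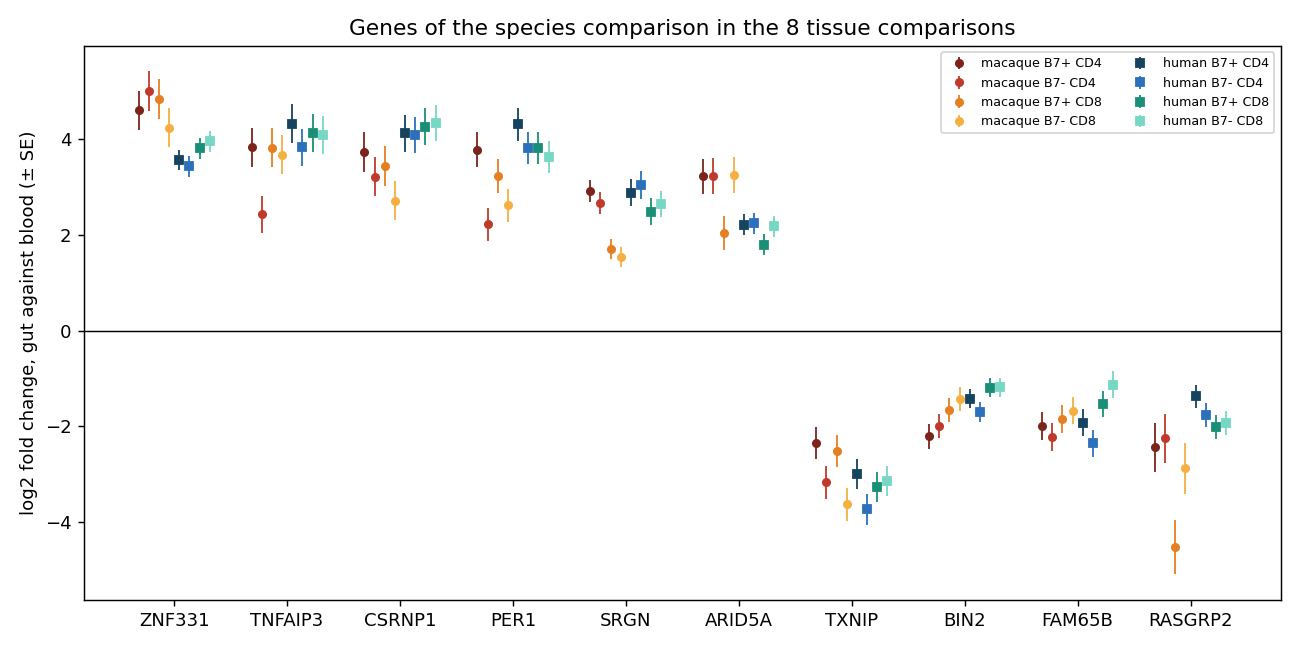
Log2 fold change between gut and blood (error bars, SE) of 10 genes in the 8 tissue comparisons, with circles for macaque (n = 4 per group) and squares for human (n = 3 per group). ZNF331 lies between 3.44 and 5.01 in the 8 comparisons, and TXNIP lies below 0 in each of them.

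The B7 label was examined next, by setting B7+ against B7- cells of the same tissue and lineage. In macaque blood CD4 cells, ITGB1 fell by 4.30 ± 0.39 on the log2 scale in B7+ cells (adjusted p = 7.0e-09, edgeR, n = 4 per group), at 112 ± 22.1 against 2205 ± 289 CPM. CCR9, the receptor for the gut chemokine CCL25, was at 266 ± 148 CPM in B7+ and 0.101 ± 0.102 CPM in B7- cells (adjusted p = 0.038). This call was lost with the replicate number as a block and without any 1 of 7 of the 8 libraries (all but B7+ replicate 4). FOSL2, an AP-1 subunit, fell by 3.92 ± 0.62 in B7+ cells and was not called by limma voom. These were the 3 genes that edgeR called, 1 risen and 2 fallen, of 12647 tested (8 in a fit on these sorts alone). Cytotoxicity genes were lower in B7+ cells as a group (0 called of 16, 9 fallen adjusted over the list alone, camera adjusted p = 3.8e-12), as were type 1 genes (0 called of 13, 6 fallen adjusted over the list alone, camera adjusted p = 4.8e-09). Proliferation genes gave 0 called of 18, 0 adjusted over the list alone, camera adjusted p = 0.025 but adjusted p = 0.56 with an estimated correlation. ITGB7, the integrin beta 7 chain, was at 1364 ± 108 CPM in B7+ and 1125 ± 217 CPM in B7- cells, with a log2 difference of 0.27 ± 0.33 that did not pass the test.

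Between B7+ and B7- CD4 cells of macaque gut, TREML2, a receptor of the TREM family (46.2 ± 31.1 against 0.92 ± 1.48 CPM), PRMT5, an arginine methyltransferase gene (72.5 ± 40.9 against 3.29 ± 5.58 CPM), and ZNF512B (23.8 ± 5.96 against 0.4 ± 0.453 CPM) were higher in B7+ cells. ITGB1 fell by 2.06 ± 0.36 on the log2 scale, beside PARP9, an interferon-induced gene of the ADP-ribosyltransferase family (-2.35 ± 0.44), and the proprotein convertase gene PCSK7 (-1.87 ± 0.33). The adjusted p of these 6 genes was at most 0.0039 (edgeR). In all 104 genes rose and 32 fell. Type 17 genes were higher in B7+ cells on balance (0 called of 16, 1 risen adjusted over the list alone, camera adjusted p = 0.0022 but adjusted p = 0.084 with an estimated correlation). Epithelial markers stood at 283 ± 163 CPM in B7+ and 8628 ± 16808 CPM in B7- libraries (2 fallen of 23, 12 adjusted over the list alone, camera adjusted p = 0.087), and B and plasma cell markers at 6329.6 ± 6968 and 632 ± 399 CPM (1 risen of 15, 1 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.89). The count of 136 was 87 without B7+ replicate 2, 339, 411 and 303 without B7- replicates 2, 3 and 4, 256 without the libraries rich in foreign markers and 522 without the low-complexity libraries. A fit on the 8 compared libraries alone called 0 genes, so the count may depend on the spread that the 10 sorts share in the fit. Limma voom with quality weights called 4, none of them among these 6.

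In macaque CD8 cells of blood, ITGB1 was the only gene called, at -1.97 ± 0.36 (adjusted p = 0.038, edgeR) and 146 ± 35.3 against 570 ± 273 CPM, while 322 genes had an unadjusted p under 0.05. That call was lost without any 1 of 7 of the 8 libraries (all but B7- of serial number 20). It was lost with the block with serial number 10 as number 1, without the foreign-marker libraries and in a fit on these sorts alone. Proliferation genes were higher in B7+ cells as a group (0 called of 18, 0 adjusted over the list alone, camera adjusted p = 5.4e-11). In gut CD8 cells, ITGAE rose in B7+ cells by 4.08 ± 0.50, from 87.2 ± 41.9 to 1502 ± 574 CPM, and ITGB7 by 2.07 ± 0.35, from 348 ± 95.8 to 1482 ± 370.4 CPM. IL7R, the interleukin 7 receptor (1.90 ± 0.32), CD7 (2.01 ± 0.34), SMIM3 (4.06 ± 0.44) and CAPG (3.25 ± 0.47) rose as well. ITGB2, the beta chain of the integrin LFA-1, fell by 2.00 ± 0.32 on the log2 scale, beside ITGA5, the alpha chain of a fibronectin receptor (-2.48 ± 0.43), KLF2 (-2.42 ± 0.40) and CD84 (-2.23 ± 0.33). The largest adjusted p of these 10 genes was 0.0010 (edgeR), and 40 genes rose and 27 fell. Type 17 genes rose (2 risen of 16, 8 risen and 1 fallen adjusted over the list alone, camera adjusted p = 4.6e-08), and egress genes were lower (1 fallen of 17, 6 adjusted over the list alone, camera adjusted p = 1.1e-04 but adjusted p = 0.052 with an estimated correlation). Stroma and endothelium markers were lower in B7+ cells, at 111 ± 62.3 against 1535 ± 1355 CPM (0 called of 11, 3 fallen adjusted over the list alone, camera adjusted p = 4.6e-08). The count of 67 was 43, 40 and 40 without B7- replicates 1, 2 and 4, 42 without B7+ replicate 2 and 118 without the foreign-marker libraries.

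In human blood CD4 cells, MCM7, a subunit of the replicative helicase, rose in B7+ cells by 1.85 ± 0.26 (n = 3 per group), PCNA, the sliding clamp of DNA polymerase, by 1.76 ± 0.26, CENPM, a centromere protein gene, by 2.50 ± 0.36, and ZWINT, a kinetochore gene, by 2.69 ± 0.43. TUBB, a beta tubulin gene (1.51 ± 0.25), CKS2, a cofactor of cyclin-dependent kinases (1.71 ± 0.29), and LAG3, an inhibitory receptor gene (2.51 ± 0.46), rose. ITGB1 fell by 2.86 ± 0.41 on the log2 scale, from 749.5 ± 86.8 CPM in B7- cells to 105 ± 30.7 CPM in B7+ cells. The other fallen genes were the interferon-induced gene HERC5 (-1.21 ± 0.27), MCC, TRAK2 and TMEM216. Over these 9 genes the adjusted p was at most 0.042 (edgeR). Proliferation genes rose (7 risen of 18, 18 adjusted over the list alone, camera adjusted p = 1.4e-34). In all 81 genes rose and 5 fell, and with the replicate number as a block 127 rose and 19 fell. A fit on these sorts alone called 259. The total of 86 was 5, 15 and 9 without B7- replicates 5, 6 and 7, 36 and 5 without B7+ replicates 6 and 7, and 53 without the foreign-marker libraries of the gut sorts. The call of HERC5 was lost without any 1 of the 6 libraries, and without the low-count filter or the foreign-marker libraries. That of LAG3 was lost without any 1 of 4, CKS2 of 3, TUBB and ZWINT of 2 and PCNA of 1.

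In human blood CD8 cells ITGB1 was the only gene called between B7+ and B7- cells, at -2.48 ± 0.40 (adjusted p = 0.043, edgeR) and 104 ± 22.0 against 576 ± 203 CPM, with 785 genes at an unadjusted p under 0.05. The call was lost without any 1 of 5 of the 6 libraries, all but B7- replicate 5, and in a fit on these sorts alone. Proliferation genes were higher in B7+ cells as a group (0 called of 18, 18 risen adjusted over the list alone, camera adjusted p = 1.3e-28). In human gut CD4 cells edgeR called 0 genes, with 745 at an unadjusted p under 0.05, while DESeq2 called 1 and limma voom 2. ITGA4, the integrin alpha 4 chain, stood at 405 ± 143 CPM in B7+ and 196 ± 67.0 CPM in B7- cells, ITGB7 at 231 ± 60.5 and 134 ± 8.03 CPM, and neither difference passed the test. The 0 became 1 without B7- replicate 6, 6 without B7+ replicate 7 and 7 without the foreign-marker libraries. Proliferation genes gave 0 called of 18, 0 adjusted over the list alone, camera adjusted p = 1.7e-13 but adjusted p = 0.37 with an estimated correlation. In human gut CD8 cells edgeR also called 0 genes, with 1103 at an unadjusted p under 0.05, and 0 with the replicate number as a block, while DESeq2 called 61 and limma voom 0. Proliferation genes were higher in B7+ cells as a group (0 called of 18, 11 risen adjusted over the list alone, camera adjusted p = 6.8e-18 but adjusted p = 0.16 with an estimated correlation), for instance RRM2, a subunit of ribonucleotide reductase, at 139 ± 55.4 against 22.6 ± 16.0 CPM. Glycolysis genes gave 0 called of 15, 5 risen adjusted over the list alone, camera adjusted p = 9.7e-07 but adjusted p = 0.16 with an estimated correlation. ITGAE was at 1054 ± 1004 CPM in B7+ and 356 ± 142 CPM in B7- cells.

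**Figure D2:**
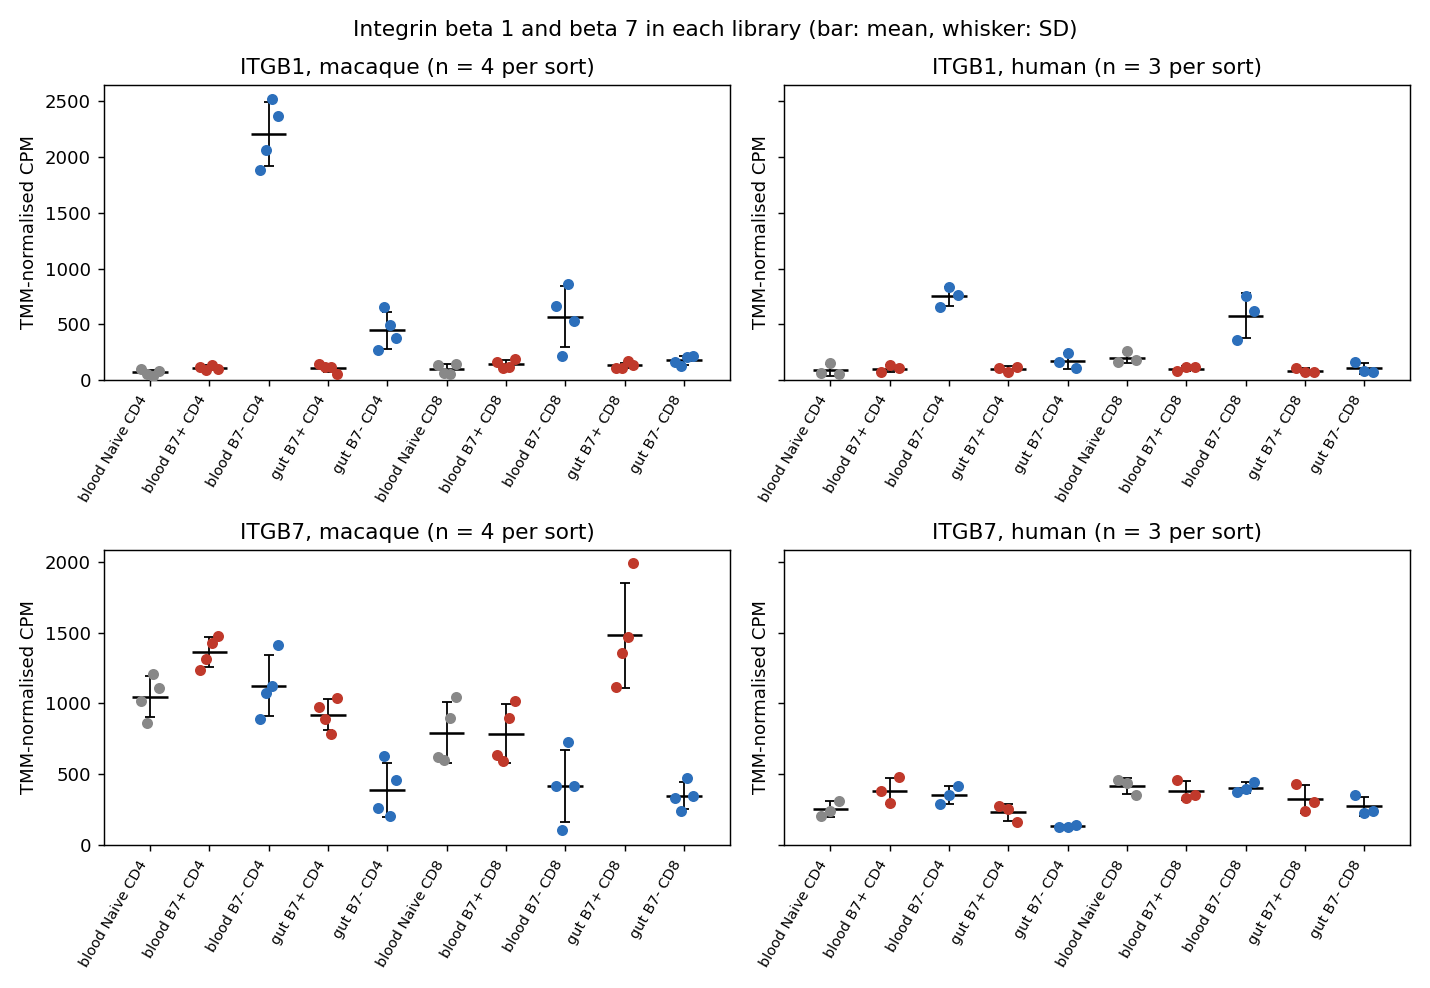
ITGB1 and ITGB7 expression (TMM-scaled CPM, 1 point per library, bar and whisker for mean and SD) in the 10 sorts of each species, with B7+ in red, B7- in blue and naive in grey. ITGB1 was called lower in B7+ cells in 5 of the 8 comparisons of B7+ with B7- cells, and ITGB7 called higher in 1.

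The B7+ and B7- cells of blood, as the mean of both sorts, were then set against naive cells. In macaque CD4 cells, VIM (1.79 ± 0.20), S100A10 (2.76 ± 0.30), STX11, a syntaxin gene of granule exocytosis (3.48 ± 0.30), and TIGIT, an inhibitory receptor (5.61 ± 0.63), rose. SATB1, a chromatin organiser of T cell development (-2.12 ± 0.31), the pyruvate dehydrogenase kinase gene PDK1 (-2.13 ± 0.31) and the antiproliferative gene BTG1 (-1.02 ± 0.16) fell. Of the antiviral genes, ISG15 rose by 3.11 ± 0.37 and APOBEC3G, a cytidine deaminase that restricts retroviruses, by 3.97 ± 0.67. The adjusted p of these 9 genes was at most 1.6e-04 (edgeR), and 401 genes rose and 113 fell. Proliferation genes rose (9 risen of 18, 15 adjusted over the list alone, camera adjusted p = 4.3e-22), as did homing receptors and integrins (9 risen of 17, 10 risen and 2 fallen adjusted over the list alone, camera adjusted p = 5.5e-13), type 1 genes (7 risen of 13, 8 adjusted over the list alone, camera adjusted p = 4.1e-14) and regulatory T cell genes (6 risen of 14, 9 adjusted over the list alone, camera adjusted p = 5.9e-11). Naive T cell genes fell (5 fallen of 18, 8 adjusted over the list alone, camera adjusted p = 6.4e-06). The total of 514 was 322, 320 and 342 without naive replicates 1, 2 and 4, and 837 without the low-complexity libraries of the gut sorts.

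Against naive macaque CD8 cells, GPR183, a receptor for oxysterols (2.25 ± 0.36), VIM (1.13 ± 0.19) and RRM2 (4.93 ± 0.86) rose, and PDK1 (-2.17 ± 0.31), ACTN1, an alpha actinin gene (-2.21 ± 0.40), BTG1 (-1.003 ± 0.16) and CD7 (-1.54 ± 0.28) fell, with adjusted p at most 0.0022 (edgeR). RRM2 was not called by limma voom. In all 84 genes rose and 63 fell. Proliferation genes rose (4 risen of 18, 13 adjusted over the list alone, camera adjusted p = 8.5e-25) and naive genes fell (6 fallen of 18, 8 adjusted over the list alone, camera adjusted p = 1.3e-07). The total of 147 was 91, 75, 47 and 68 without naive replicates 1 to 4, 95 and 96 without B7+ replicates 2 and 4, and 286 without the low-complexity libraries of the gut sorts.

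Against naive human CD4 cells, FAS, a death receptor (4.06 ± 0.31), PDCD1 (3.82 ± 0.66), the chemokine receptor CXCR3 (4.24 ± 0.43) and GAPDH (1.58 ± 0.21) rose. BACH2, a repressor of effector differentiation (-2.45 ± 0.31), TGFBR2, a TGF-beta receptor (-1.29 ± 0.17), and PDK1 (-2.07 ± 0.27) fell, with adjusted p at most 6.7e-04 (edgeR). In all 969 genes rose and 406 fell. Proliferation (16 risen of 18, 18 adjusted over the list alone, camera adjusted p = 2.3e-27) and glycolysis genes rose (8 risen of 15, 10 adjusted over the list alone, camera adjusted p = 2.1e-08). Type 17 genes (9 risen of 16, 11 adjusted over the list alone, camera adjusted p = 2.6e-10), homing receptors and integrins (8 risen of 17, 10 risen and 1 fallen adjusted over the list alone, camera adjusted p = 1.6e-09) and inhibitory receptors rose (6 risen of 11, 6 adjusted over the list alone, camera adjusted p = 1.5e-04). Follicular helper genes gave 2 risen of 13, 4 adjusted over the list alone, camera adjusted p = 0.0054 but adjusted p = 0.20 with an estimated correlation, and type 2 genes 1 risen of 8, 5 adjusted over the list alone, camera adjusted p = 0.0045 but adjusted p = 0.20 with an estimated correlation. Naive genes fell (9 fallen of 19, 1 risen and 13 fallen adjusted over the list alone, camera adjusted p = 3.5e-08). The total of 1375 was 754 and 897 without naive replicates 5 and 6.

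Against naive human CD8 cells, HNRNPLL, a splicing regulator of CD45 (2.22 ± 0.25), GPR183 (1.76 ± 0.24) and PDCD1 (3.38 ± 0.64) rose. LEF1 (-2.31 ± 0.29), CCR7 (-3.20 ± 0.47) and IL6ST, a signalling chain of interleukin 6 receptors (-2.08 ± 0.29), fell, with adjusted p at most 0.0078 (edgeR). DUSP4, a MAP kinase phosphatase gene, was at 4.34 ± 1.42 CPM in B7+, 4.46 ± 0.56 CPM in B7- and 0.244 ± 0.301 CPM in naive cells (adjusted p = 0.00098). Its call was lost with voom, and PDCD1 was not called without naive replicate 7. In all 107 genes rose and 104 fell. Proliferation (7 risen of 18, 17 adjusted over the list alone, camera adjusted p = 3.0e-26) and type 17 genes rose (6 risen of 16, 11 risen and 1 fallen adjusted over the list alone, camera adjusted p = 1.9e-13), and naive genes fell (9 fallen of 19, 1 risen and 13 fallen adjusted over the list alone, camera adjusted p = 6.2e-16). Myeloid markers moved with this comparison (0 called of 16, 6 risen adjusted over the list alone, camera adjusted p = 3.6e-08 but adjusted p = 0.17 with an estimated correlation), at 292 ± 168 CPM in B7+, 510.3 ± 426 in B7- and 41.3 ± 46.4 in naive libraries. The total of 211 was 136, 76 and 46 without naive replicates 5, 6 and 7, 131 and 109 without B7+ replicates 5 and 7, and 108 without B7- replicate 7.

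**Figure D3:**
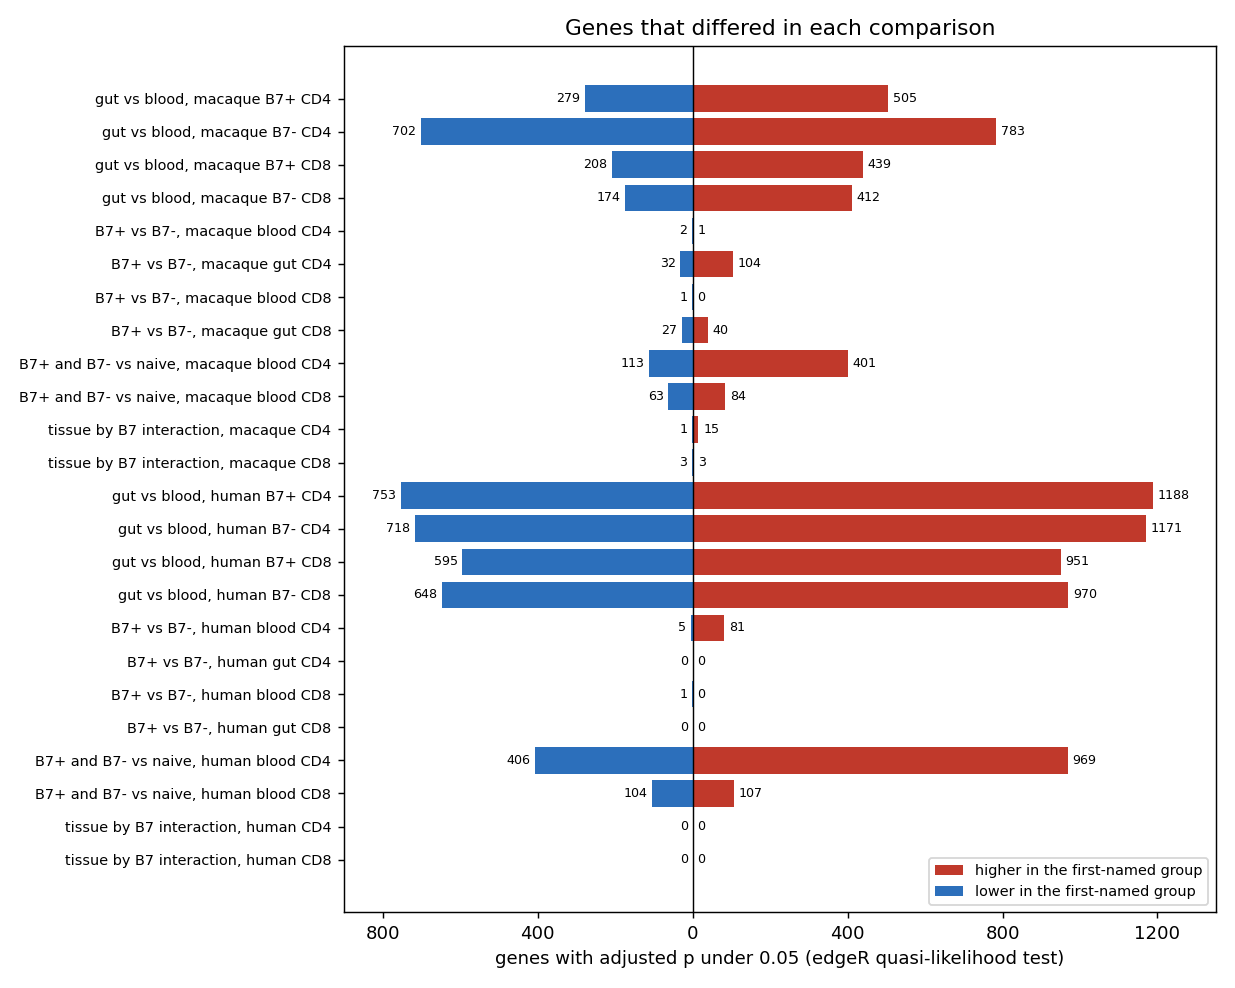
Number of genes called higher (bars to the right) or lower (bars to the left) in each of the 24 comparisons, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The 8 tissue comparisons call 586 to 1941 genes each and the 8 comparisons of B7+ with B7- cells 0 to 136. For an interaction, higher means that the B7+ minus B7- difference was higher in gut than in blood.

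Whether the difference between B7+ and B7- cells itself differed between tissues was tested as an interaction. In macaque CD4 cells the B7+ minus B7- difference on the log2 scale was higher in gut than in blood by 2.25 ± 0.49 for ITGB1, which was lower in B7+ cells of both tissues, and by 2.87 ± 0.54 for ZDHHC18, a palmitoyltransferase gene. For the B cell gene CD79A the interaction was -3.68 ± 0.74 (adjusted p at most 0.049 for the 3 genes, edgeR). The call of ITGB1 was lost without any 1 of 13 of the 16 libraries, with RLE factors, with the block, with voom and without the foreign-marker libraries. That of CD79A was lost without any 1 of 6 and with voom, and that of ZDHHC18 without blood B7+ replicate 2 or 4 and with voom. In all 15 genes had a higher and 1, CD79A, a lower difference in gut. Egress genes gave 0 called of 17, 0 adjusted over the list alone, camera adjusted p = 0.50, and B and plasma cell markers 1 fallen of 15, 3 adjusted over the list alone, camera adjusted p = 0.18. The count of 16 was 29, 96, 123 and 31 without gut B7- replicates 1 to 4, 6 without gut B7+ replicate 2, 4, 2, 6 and 5 without blood B7+ replicates 1 to 4, and 9, 5, 7 and 6 without blood B7- replicates 1 to 4. It was 102 without the foreign-marker libraries, 230 without the low-complexity libraries and 7 with edgeR's RLE scaling factors.

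In macaque CD8 cells the difference between B7+ and B7- was higher in gut than in blood for SMIM3 (3.82 ± 0.57), CAPG (3.73 ± 0.63) and ITGAE (3.13 ± 0.63), and lower for CD84 (-2.31 ± 0.45) and RBM38 (-1.96 ± 0.40). TREML2 was called as well, at 0.349 ± 0.122 CPM in gut B7+, 15.0 ± 5.38 in gut B7-, 64.7 ± 18.7 in blood B7+ and 67.2 ± 42.0 CPM in blood B7- cells. These were the 6 genes called, with adjusted p at most 0.0496 (edgeR). The calls of ITGAE, RBM38 and CD84 were lost without any 1 of 11, 13 and 11 of the 16 libraries. That of ITGAE was also lost with the replicate block and without the low-complexity libraries, and that of TREML2 with voom. Type 17 genes gave 0 called of 16, 2 risen adjusted over the list alone, camera adjusted p = 1.6e-06. The count of 6 was 16 and 10 without gut B7+ replicates 1 and 3, 20 without the foreign-marker libraries, and 3 without any 1 of gut B7- replicate 3, blood B7+ replicates 1 and 2 and the blood B7- libraries of serial numbers 10 and 20. In human cells edgeR called 0 genes in CD4 and 0 in CD8 cells, with 913 and 541 at an unadjusted p under 0.05, while DESeq2 called 52 and 33 and limma voom 0 and 0. The 0 in CD4 cells became 2 without gut B7+ replicate 7 and 7 without the foreign-marker libraries. Virus restriction genes in human CD4 cells gave 0 called of 13, 0 adjusted over the list alone, camera adjusted p = 0.0026.

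Lists of lineage and of further cell types follow. CD40LG, the ligand of CD40, was at 40.2 ± 46.7 CPM in human blood B7+ CD8 cells, 50.7 ± 27.7 CPM in B7- CD8 cells and 1.61 ± 1.22 CPM in naive CD8 cells (adjusted p = 0.0012, edgeR), and the CD4 lineage list it belongs to was higher than in naive cells (1 risen of 3, 3 adjusted over the list alone, camera adjusted p = 1.8e-07). The CD8 lineage list was higher in gut than in blood B7+ CD4 cells of macaque (1 risen of 3, 2 adjusted over the list alone, camera adjusted p = 0.031 but adjusted p = 0.16 with an estimated correlation). ITGB7, CD80 and CD86, the genes whose products a B7 label could name, were as a list higher in macaque B7+ and B7- CD4 cells than in naive CD4 cells (1 risen of 3, 2 adjusted over the list alone, camera adjusted p = 0.0017). Markers of red cells and platelets went down in gut B7- CD4 cells of humans (1 fallen of 7, 2 adjusted over the list alone, camera adjusted p = 0.0066 but adjusted p = 0.093 with an estimated correlation). NK and gamma-delta T cell markers were higher in macaque blood B7+ and B7- CD8 cells than in naive CD8 cells (0 called of 7, 1 risen adjusted over the list alone, camera adjusted p = 6.7e-05). Mast cell markers gave 1 risen of 5, 1 adjusted over the list alone, camera adjusted p = 0.070 in human B7+ CD4 cells of gut against blood, and in macaque 1 of them was tested, too few for a list test.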

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

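The values of single libraries below were compared within each macaque group of 4 by a fixed rule, which marks a library whose gap to its nearest neighbour takes most of the group's range, and the tests by other splits of the libraries were chosen after the results were seen. The rule marked 14 of the 140 group measures tested (14 measures in 10 groups), where chance alone marks about 1 in 20, and human groups of 3 were not tested.

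Lineage genes stood apart in several libraries. CD4 was at 446 CPM in macaque gut B7+ CD4 replicate 3 against 763 to 796 CPM in the other 3 libraries, and CD8B in the same library at 20.7 CPM against 1.35 to 1.65 CPM. CD8B was at 71.0 CPM in gut B7- CD4 replicate 4 (others 1.43 to 3.22 CPM) and at 16.1 CPM in blood B7+ CD4 replicate 4 (1.23 to 1.55 CPM). CD4 was at 13.0 CPM in blood naive CD8 replicate 4 (0.350 to 0.404 CPM), at 11.4 CPM in gut B7+ CD8 replicate 4 (1.17 to 1.39 CPM) and at 14.8 CPM in blood B7+ CD8 replicate 1 (0.504 to 1.11 CPM). CD8A was at 1057 CPM in naive CD8 replicate 3 (1312 to 1371 CPM).

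Stroma and endothelium markers were at 0.437 CPM in naive CD8 replicate 3, where the other libraries held 36.3 to 64.4 CPM, and at 17.8 CPM in gut B7- CD4 replicate 2 against 430 to 599 CPM. Unmapped reads took 42.8% of gut B7- CD4 replicate 1 (others 4.56% to 7.39%), 9.47% of gut B7+ CD8 replicate 2 (3.65% to 4.40%) and 3.20% of gut B7- CD8 replicate 2 (3.47% to 3.52%). In blood B7- CD4 replicate 1, 10803 genes were detected (11230 to 11272).

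The difference between B7+ and B7- cells differed between gut and blood for 16 genes in macaque CD4 cells and 6 in macaque CD8 cells by the interaction test of edgeR. In fits on the compared libraries alone these counts were 3 and 14. Of 40 splits of the libraries drawn for each, 3 gave as many genes as the real one in CD4 cells (highest other 131) and 2 in CD8 cells (highest other 315). Chance could not be excluded for either count by this test. Splits that call several times the real count point to a structure of these libraries other than the tested one, and such splits mix gut with blood libraries.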

How the results depend on the processing

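The fits without the foreign-marker and without the low-complexity libraries were chosen after the results were seen, and all other alternatives before the data were examined. Counts of called genes are given throughout in the order B7+ CD4, B7- CD4, B7+ CD8, B7- CD8 for tissue and species comparisons, blood CD4, gut CD4, blood CD8, gut CD8 for B7+ against B7-, and CD4, CD8 for the others, macaque before human. The numbers called by edgeR with all libraries were 784, 1485, 647, 586, 1941, 1889, 1546 and 1618 between tissues, 3, 136, 1, 67, 86, 0, 1 and 0 between B7+ and B7-, 514, 147, 1375 and 211 against naive cells, 16, 6, 0 and 0 for the interactions and 353, 526, 297 and 289 shared by the species. DESeq2 called 1640, 2527, 1475, 1235, 3055, 2993, 2466 and 2645, then 279, 987, 174, 586, 507, 1, 89 and 61, then 1166, 641, 2364 and 824, then 497, 317, 52 and 33, with 635, 825, 481 and 483 shared. Limma voom with quality weights called 1434, 659, 1703, 2095, 2208, 4041, 1635 and 2291, then 27, 4, 7, 329, 766, 2, 4 and 0, then 1664, 867, 2550 and 743, then 2, 78, 0 and 0, with 544, 380, 493 and 681 shared. The cause of these differences was not tested. On counts simulated from edgeR's own model DESeq2 made 29.5% to 64.5% false calls and voom 6.98% to 33.6%, which need not hold for the real libraries. No library lay under 25% of the median depth, so leaving out such libraries has no value. RLE factors moved 1 count by over 1.5 times, the macaque CD4 interaction from 16 to 7, and shifted the median of all genes by at most 0.084 on the log2 scale. Without the low-count filter 1 count moved, human blood CD8 B7 from 1 to 2.

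With the replicate number as a block, B7+ against B7- in human blood CD4 cells went from 86 to 146 and human naive CD8 from 211 to 369, and no other count moved by over 1.5 times. With serial number 10 counted as number 1, macaque blood CD8 B7 went from 1 to 0 and the macaque CD8 interaction from 6 to 10. As a hint from the data and not from the design, 36 of 40 macaque libraries deviated most like those of their own number (38 with serial number 10 as number 1, whose mean correlation of deviations was 0.073 with number 1 and -0.014 with number 2), and 29 of 30 human libraries. The cause was not tested. Of the list tests 251 passed with the preset correlation, 97 with an estimated correlation, 256 with the block and 226 without the foreign-marker libraries. Of the 251, 4 were lost or turned with the block and 37 without the foreign-marker libraries. At an adjusted p under 0.01 in both species 176, 206, 146 and 151 genes were shared, fewer by construction.

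Without the foreign-marker libraries the counts that moved by over 1.5 times were 658 in human B7- CD4 cells between tissues, 256, 0 and 118 for B7 in macaque gut CD4, blood CD8 and gut CD8, 53 and 7 in human blood and gut CD4, 102 and 20 for the macaque interactions, 7 for the human CD4 interaction, and 257 shared by the species in B7- CD4 cells. Without the low-complexity libraries they were 1378 and 989 between tissues in macaque B7+ CD4 and B7- CD8 cells, 522 for B7 in macaque gut CD4, 837 and 286 against naive CD4 and CD8 cells, and 230 for the macaque CD4 interaction. Blood comparisons are among these because the 10 groups of a species share the scaling and the estimate of the spread. Leaving out each library in turn gave 490 to 841, 976 to 1726, 423 to 584, 372 to 474, 1127 to 1687, 1062 to 1683, 993 to 1303 and 1074 to 1325 genes between tissues, 2 to 4, 87 to 411, 0 to 1, 40 to 88, 5 to 88, 0 to 6, 0 to 1 and 0 to 0 for B7, 320 to 453, 47 to 133, 754 to 1266 and 46 to 284 against naive cells, 2 to 123, 3 to 16, 0 to 2 and 0 to 0 for the interactions and 266 to 340, 362 to 569, 214 to 277 and 207 to 258 shared by the species.

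Of the fold changes of named genes under each alternative, 2611 kept their direction and their side of the threshold, 156 kept the direction and no longer passed, and 5 passed where the main test had not, all in macaque (SAMHD1 in B7- CD4 with the block and without the low-complexity libraries and in B7+ CD8 with voom, and CCR7 against naive CD8 with voom and without the low-complexity libraries). SAMHD1 in macaque B7- CD8 cells, which had not passed, lay at -0.65 to 0.015 as each library was left out and changed sign without gut replicate 3. Depth limits what can be seen of low genes, since 3 reads stand for up to 0.658 CPM in macaque libraries (gut B7- CD4 replicate 1, the shallowest) and up to 0.285 CPM in human libraries. In simulated counts of the macaque gut B7- CD4 comparison with blood 1.47% of genes changed 2-fold were recovered.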

Other observations

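The tests of explanations and of other splits in this part were chosen after the results were seen, and the gene lists were fixed before.

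Members of the follicular helper and regulatory T cell lists, not described above, rose in gut in some CD4 and CD8 sorts. ICOS, a co-stimulatory receptor, rose in human gut B7- CD4 cells by 3.45 ± 0.37 and in gut B7+ CD8 cells by 3.19 ± 0.37 (n = 3 per group), and in macaque by 2.34 ± 0.42 and 2.70 ± 0.43 (n = 4 per group). BCL6, the transcription factor that directs follicular helper cells, rose in human B7- CD4 cells by 4.27 ± 0.60, with CXCL13, the chemokine of B cell follicles, at 67.6 ± 58.5 CPM in gut and 0.354 ± 0.362 CPM in blood. As a list the follicular helper genes rose in macaque B7- CD4 cells (6 risen of 13, 8 adjusted over the list alone, camera adjusted p = 2.3e-06) and human B7- CD4 cells (6 risen of 13, 8 adjusted over the list alone, camera adjusted p = 2.6e-08), and in human B7+ CD8 cells the call rested on the preset correlation (3 risen of 13, 6 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.031 but adjusted p = 0.37 with an estimated correlation). Macaque B7+ CD8 cells gave 2 risen of 13, 3 risen and 2 fallen adjusted over the list alone, camera adjusted p = 0.73. CTLA4 rose by 4.02 ± 0.56 in human and 3.11 ± 0.68 in macaque B7+ CD8 cells, and TNFRSF9, the co-stimulatory receptor 4-1BB, by 4.13 ± 0.81 and 4.61 ± 1.23. Regulatory T cell genes rose in B7+ CD8 cells (7 risen of 15, 7 adjusted over the list alone, camera adjusted p = 2.4e-05 in human and 4 risen of 14, 5 adjusted over the list alone, camera adjusted p = 1.0e-04 in macaque). FOXP3, the regulator of those cells, was not among the risen genes there, at 1.90 ± 0.991 CPM in human gut and 2.02 ± 2.20 CPM in blood B7+ CD8 cells. Inhibitory receptors rose in human gut B7- CD4 cells (6 risen of 11, 6 adjusted over the list alone, camera adjusted p = 1.1e-05). Over the genes given with a fold change the adjusted p was at most 0.019 (edgeR), for TNFRSF9 in macaque. That call was lost without gut replicate 2 and without blood replicate 1, 2 or 4.

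The glycolysis list held genes that rose and genes that fell in gut. SLC2A3, the glucose transporter GLUT3, rose in macaque B7+ CD4 cells by 3.80 ± 0.46 and in human B7+ CD8 cells by 3.22 ± 0.22. PFKFB3, which makes the activator of phosphofructokinase, rose by 3.67 ± 0.75 and 5.39 ± 0.45, and LDHA, which makes lactate, by 1.20 ± 0.18 and 1.57 ± 0.17. HK1, which encodes a hexokinase, went down in macaque B7+ CD4 cells (-0.97 ± 0.30) and human B7- CD8 cells (-0.96 ± 0.20). The macaque call was lost without any 1 of 5 of the 8 libraries, without the low-count filter and without the foreign-marker libraries. As a list glycolysis genes rose in macaque B7+ CD8 cells (5 risen of 15, 9 adjusted over the list alone, camera adjusted p = 1.0e-06), and in macaque B7+ CD4 cells (6 risen and 1 fallen of 15, 6 risen and 2 fallen adjusted over the list alone, camera adjusted p = 9.3e-04 but adjusted p = 0.12 with an estimated correlation) and human B7+ CD8 cells (5 risen of 15, 5 adjusted over the list alone, camera adjusted p = 1.3e-06 but adjusted p = 0.057 with an estimated correlation) on the preset correlation. SAMHD1, which depletes the nucleotides that reverse transcription needs, was lower in gut in each of the 4 human sorts, at -0.93 ± 0.17, -1.64 ± 0.18, -1.15 ± 0.17 and -1.62 ± 0.18 (B7+ CD4, B7- CD4, B7+ CD8 and B7- CD8). The genes of this paragraph said to rise or go down had an adjusted p of at most 0.044 (edgeR). In macaque SAMHD1 was at -1.08 ± 0.60, -1.45 ± 0.60, -1.48 ± 0.60 and -0.24 ± 0.59 and passed the test in none of the 4. Interferon response genes were lower in gut B7- CD4 cells of macaque on the preset correlation, as given above. Human cells gave 1 risen and 3 fallen of 25, 1 risen and 4 fallen adjusted over the list alone, camera adjusted p = 0.055. Whether the species differ in these genes was not tested.

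The 121 genes risen in gut in all 8 tissue comparisons held 10 immediate early genes (0.229 expected). If RNA of epithelial, B or plasma cells were the whole source, most of these genes should be lost without the libraries richest in it. Most were still risen in all 8. That none of the 23 epithelial and 15 B and plasma cell markers was among the 121 decides nothing. Human B7+ CD8 cells called no epithelial marker, and macaque B7+ CD4 cells few B and plasma cell markers. The most abundant of those markers were CLDN4 and PIGR (3062 ± 6021 and 1476 ± 2951 CPM in macaque gut B7- CD4 cells) and JCHAIN (5833 ± 6668 CPM in macaque gut B7+ CD4 cells). In a blood sort 10 epithelial markers reached 1 CPM in each species, as did 15 (macaque) and 10 (human) B and plasma cell markers. The stroma markers COL1A1 and COL3A1 were among the 121, and like the immediate early genes FOS and BTG2 they were no longer risen in all 8 without those libraries. Fewer libraries can end calls too. Kept gut libraries held RNA of other cells, which stays open for part of the 121. Handling of biopsies could also raise immediate early genes. All gut and no blood libraries came from biopsies, so handling and tissue cannot be told apart for any gene called between gut and blood.

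Between B7+ and B7- cells of macaque gut, 136 CD4 genes were called. If low-complexity libraries in the B7- group were the whole cause, most calls should be lost without them, but 92 of the same genes were called in the same direction. Without the libraries rich in epithelial, B or plasma cell markers 77 were. Neither count decides, since both fits called more genes in all (522 and 256). Kept B7+ libraries also held 829 and 1588 CPM of B and plasma cell markers. A fit on the 8 compared libraries alone called 0 genes, so the spread shared with other sorts may matter. A difference of the cells themselves stays open too.

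ITGB1 was lower in B7+ than in B7- cells in each of the 8 comparisons and called in 5 of them. A candidate explanation is that the B7 label marks a sort on integrin beta 7, whose alpha 4 partner also pairs with integrin beta 1. ITGB7 was higher in B7+ cells in 7 of the 8 comparisons but called risen in 1, and CD80 and CD86, genes of the B7 family of co-stimulatory ligands, passed the test in none of the 8 (smallest unadjusted p = 0.19 and smallest adjusted p = 0.67, edgeR). The level of a transcript need not follow the surface protein that a sort reads, so a sort on integrin beta 7 and other meanings of the label cannot be told apart from these values.

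Other splits of the compared libraries, in fits on those libraries alone, show whether chance can give as many genes. Between tissues chance was an unlikely source in macaque, where the real split alone of 35 gave the count. It called 629, 384, 618 and 1363 genes for B7+ CD4, B7- CD4, B7+ CD8 and B7- CD8 (highest other 0). The human libraries allow 10 splits, so the share is never under 0.1, and the real split gave 829, 2067, 739 and 1456 genes against at most 0, 0, 1 and 0. For B7+ against B7- chance was an unlikely source in macaque blood CD4 (8 genes, highest other 2) and gut CD8 cells (50, highest other 0). Each was the highest of 35 splits. In macaque gut CD4 (highest other 0) and blood CD8 cells (highest other 4) the real count was 0, which all 35 splits reach whatever the data, so nothing on chance follows. With 10 splits in human, the values were 259 genes in blood CD4 (highest other 0), 0 in gut CD4 (1), 0 in blood CD8 (0) and 0 in gut CD8 cells (1), and in the last 3 all 10 splits reach 0 by construction. Against naive cells the real split called 1188, 628, 1897 and 172, and the others of 40 drawn at most 1, 0, 36 and 11. This makes chance an unlikely source. The drawn splits took no account of the replicate number, by which the human CD4 libraries were correlated. For the human interactions the real count was also 0, which all 40 drawn splits reach by construction (highest other 0 in CD4 and 1 in CD8 cells). The genes shared by the species numbered 238, 186, 193 and 473 in these fits. The others of 100 drawn gave 0, but as other splits of each species called at most 1 gene, these draws add nothing on chance.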
